A study of Helicoverpa armigera with 24 samples.

How the data were processed

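Total RNA of 24 pools (gut and rest of body, 3 diets, 4 pools of 5 larvae each) was labelled with Cy3 after addition of Agilent spike-in RNA and hybridised to 1-colour Agilent arrays, per the labels. The deposited files hold the scanner output of each array as intensity values of single spots on a linear scale. Per the file headers these intensity values were extracted with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. The processed intensity is background-subtracted and detrended but not normalized between arrays, per the file headers. Flags of each spot (well above background, saturated, non-uniform or population outlier) were set by the same software, per the file headers. Each array held 43803 non-control probes with 1 spot each and 1417 control spots.

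The series also has a table of processed log2 values from the authors. These deposited log2 values were compared with the scanner values: they matched quantile-normalized log2 processed signals centred on each probe's median over the 12 arrays of its tissue, with a slope of 1.00 and a correlation of 1.00 in each tissue, so that scale, centring and direction were all settled. Column medians of that table lay between -0.03 and 0.02 in gut and between -0.06 and 0.07 in rest of body. Because the 2 tissues were centred apart, the table was not used for gut against rest of body.

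In the main setting the log2 processed signal of each non-control probe was taken relative to the 75th percentile of its array. Probes were kept if well above background on at least 3 of the 4 arrays of at least 1 group in the fit, and probes with an outlier-flagged spot on an array of the fit were left out, 51 over all arrays. No non-control spot was saturated. Limma 3.58.1 in R 4.3.3 (lmFit and eBayes) gave log2 changes, standard errors and Benjamini-Hochberg adjusted p-values, and a probe was called at an adjusted p under 0.05 and at least a 2-fold change. Within-tissue comparisons used the 12 arrays of the tissue, and comparisons across tissues used all 24 arrays. Groups, tests, alternatives and the rule for named probes were fixed before the data were examined. The rule, where no table pairs probes with genes, names at most 2 probes that rose and 2 that fell per comparison, those with the largest changes whose arrays of both groups do not overlap; the condition that a named probe be well above background on at least 3 of 4 arrays of each group compared was added to it. For the tissue difference, called probes are ranked by size.

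The files and the reference table do not pair the probes with gene names, so the 29 gene lists fixed beforehand could not be matched and were not analysed here. In their place, and chosen after seeing the data, probes were grouped as brighter in gut or in rest of body (adjusted p under 0.05 and at least 4-fold) on the diet that took no part in the comparison, and tested with camera at a preset correlation of 0.01 and with an estimated one.

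Gut and rest-of-body samples share pool numbers, and the labels' protocols describe tissues pooled by biological replicate. Deviations from group means were compared between same-numbered gut and rest-of-body arrays over 31234 probes. They correlated with 0.195 to 0.558 in all 12 pairs, above the 0.1 set as a threshold. Some arrays of other numbers also passed 0.1, up to 0.373 for gut low-diet pool 2, so the threshold alone did not set pairs apart. Each gut array correlated best with its own number, but by as little as 0.200 against 0.190 in control pool 4. On this basis the numbers were taken to pair samples across tissues. Averages over tissues were therefore made within pools.

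Other settings were quantile normalization, median centring, the percentile over probes well above background on all arrays, normexp background correction with an offset of 50, the authors' log2 table, no filter and a strict filter on dim probes, adjusted p without a fold threshold, limma treat against 1.5-fold, other sets of arrays in the fit, array weights, the replicate block, and leaving out each replicate, for which the filter of the full fit was kept. The mean-signal column was not in the files, so normexp used the median spot and background signals. Scaling to 6 E1A spike-in probes and leaving out low-diet pool 4 were added after seeing the data. Each slide held 1 group, so no fit with the slide as a block could be made, and no table allowed 1 probe per gene.

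The fits were tested on simulated arrays with the real probe means and spreads. For the high diet in gut (32680 probes), 52 of 66 probes changed 4-fold, 15 of 67 changed 2-fold and 0 of 67 changed 1.5-fold were called, with 5 unchanged probes called. For rest of body (33510 probes) the corresponding numbers were 44, 19 and 0, with 4 unchanged probes called. For the tissue difference on the high diet (34917 probes) they were 34, 8 and 0, with 5 unchanged probes called. With pool effects simulated and the pool as a block they were 19, 0 and 0, with 1. For the average over tissues they were 54, 22 and 1, with 2. Far fewer probes were changed here than were called in the real data, and the noise was independent between probes. These shares therefore need not hold for the real fits.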

Results

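Expression was measured in larvae of Helicoverpa armigera, the cotton bollworm, which had fed for 3 days on an artificial diet without gossypol or with gossypol at 0.016% or 0.16% (w/v). Gossypol is a phenolic compound of cotton plants that is toxic to many insects. The larvae were newly moulted into their last larval instar at the start of feeding. Gut and rest of body were taken apart, each pool held tissue of 5 larvae, and each of the 6 combinations of tissue and diet had 4 pools, so 24 arrays were available. The 0.016% and 0.16% diets are called the low and the high diet. Between 29769 and 33805 of the 43803 non-control probes were well above background on an array, and the 75th percentile of the processed signal lay between 457 and 911. Correlations of log2 levels between arrays of a group ranged from 0.935 to 0.986 across probes, which are not independent replicates. The number of arrays limits the precision of each value. The files do not pair probes with genes, so probes are given by their identifiers, at most 2 that rose and 2 that fell per comparison, and groups of probes are described by the tissue in which they were brighter. Each group of 4 arrays lay on a slide of its own, so slide and group cannot be told apart in any comparison. Levels are log2 signals relative to the 75th percentile of their array, and a called probe passed a limma adjusted p of 0.05 with at least a 2-fold change.

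The first question was which probes differed between gut and rest of body without gossypol. Whether several probes read the same transcript is not known, so counts of probes are not counts of transcripts. Of 34917 probes tested, 7186 were higher and 8152 lower in gut, 15338 in all. Har_00050789 was higher in gut by 9.87 on the log2 scale (SE 0.81, limma adjusted p = 2.65e-09), with a level of 5.60 ± 0.93 (SD, n = 4) in gut and -4.26 ± 1.53 (SD, n = 4) in rest of body. Har_00050436 was higher in gut by 9.73 (SE 1.19, limma adjusted p = 7.14e-07); its rest-of-body level was -1.90 in control pool 4 and between -5.85 and -5.34 in the other pools. Har_00029748 had a difference of -11.04 (SE 1.18, limma adjusted p = 1.14e-07), from -5.46 ± 1.70 (SD, n = 4) in gut to 5.58 ± 0.47 (SD, n = 4) in rest of body. Har_00106261 had a difference of -10.81 (SE 0.95, limma adjusted p = 6.65e-09). Well above background on all 4 gut arrays and on no rest-of-body array of the control diet were 669 probes, of which 663 were among the called ones, with a median difference of at least 7.87-fold. The reverse held for 568 probes, of which 536 were called, with a median of at least 3.18-fold. These bounds set the bright group's mean against the higher of the dim probe's own signal and the lowest signal well above background on each array. The spike-in reference moved the median difference of all tested probes from -0.19 to -0.31. The control probe DCP_1_7 relative to DCP_1_0 also differed between these 2 slides, by 1.07 on the log2 scale (exact permutation p = 0.0286, two-sided). This p-value, and those given below for these control probes, set the arrays of a slide against those of another. They rest on the spread within slides and do not measure how slides vary.

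**Figure D1:**
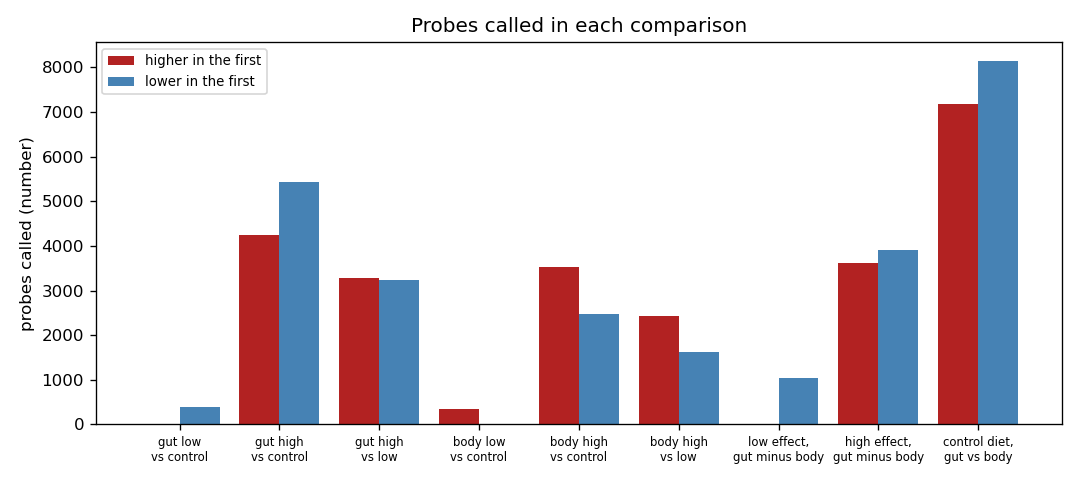
Number of probes called higher (red) and lower (blue) in each comparison, with the comparisons along the horizontal axis and the number of probes on the vertical axis. In gut 4234 probes rose and 5437 fell on the high diet, against 4 and 387 on the low diet.

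The effect of the high diet in gut was tested over 32680 probes. On the high diet 4234 probes rose and 5437 fell, 9671 in all, and 1658 of the risers and 1941 of the fallers changed at least 4-fold. Har_00210099 rose by 8.49 on the log2 scale (SE 1.75, limma adjusted p = 0.00424), from -2.82 ± 0.87 (SD, n = 4) to 5.66 ± 1.04 (SD, n = 4). Har_00185667 rose by 8.44 (SE 1.76, limma adjusted p = 0.0044). Har_00175686 fell by 7.94 (SE 2.80, limma adjusted p = 0.0363), and its mean hid a wide spread, with levels of 7.06 and 5.72 in high-diet pools 1 and 2 and of -7.86 and -5.34 in pools 3 and 4, against 7.83 ± 0.36 (SD, n = 4) on the control diet. Har_00121979 fell by 7.77 (SE 2.80, limma adjusted p = 0.0396). Both called falls of these probes were lost in 6 of the fits that left out 1 array. Levels of Har_00175686 and Har_00121979 ran close together over the arrays, such as 7.06 and 7.41 in high-diet pool 1. They may not be separate findings. Of 3529 probes at least 4-fold brighter in gut than in rest of body on the low diet, which took no part in this comparison, 1016 rose and 694 fell. Of 3703 probes brighter in rest of body by the same rule, 239 rose and 1259 fell. The shift of the second class was called by camera with a preset correlation (adjusted p = 0.000149), and the call was lost with an estimated correlation (adjusted p = 0.708 with an estimated correlation). For the first class the corresponding values were adjusted p = 0.0421 and adjusted p = 0.791 with an estimated correlation. Well above background on all 4 high-diet arrays and on no control array were 178 probes, of which 164 were among the called ones, with a median rise of at least 3.65-fold. The reverse held for 192 probes, of which 181 were called, with a median fall of at least 2.36-fold. The balance of directions depended on the scaling: with the E1A spike-in probes as reference 7001 probes rose and 2905 fell, and the median of all tested probes moved from -0.04 to 0.31. With normexp background correction 4744 probes were called.

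In rest of body 33510 probes were tested against the high diet, of which 3530 rose and 2469 fell, 5999 in all. Without the 2-fold threshold more fell than rose, 7364 against 5705. Har_00175646 rose by 10.06 on the log2 scale (SE 2.23, limma adjusted p = 0.00713), from -2.82 ± 0.65 (SD, n = 4) to 7.24 ± 0.65 (SD, n = 4). Har_00185667, also named in gut, rose by 10.01 (SE 2.19, limma adjusted p = 0.0069). Har_00185667, Har_00175646 and Har_00210099 had close levels on all arrays, such as 6.58, 6.45 and 6.69 in gut low-diet pool 4. They may therefore not be separate findings. Har_00091564 fell by 5.92 (SE 2.04, limma adjusted p = 0.0408) and Har_00064268 fell by 5.75 (SE 1.31, limma adjusted p = 0.00808). The call on Har_00091564 was lost in 5 of the fits that left out 1 array. Of 2840 probes brighter in gut, 511 rose and 149 fell in rest of body, and of 4851 probes brighter in rest of body 1059 rose and 649 fell. Camera called both upward with the preset correlation (adjusted p = 0.000427 and adjusted p = 0.00381), and neither with the estimated one (adjusted p = 0.417 with an estimated correlation and adjusted p = 0.159 with an estimated correlation). Probes well above background on all 4 high-diet arrays and on no control array numbered 230, of which 229 were called, with a median rise of at least 8.19-fold. The reverse held for 271 probes, of which 137 were called, with a median fall of at least 1.38-fold. DCP_1_7 minus DCP_1_0 was -3.94 on the high-diet slide and -4.55 on the control slide, a difference of 0.61 (exact permutation p = 0.0286, two-sided). For the control probes DCP_22_7 and DCP_22_0 the corresponding difference was 0.06 (exact permutation p = 0.686, two-sided). Median centring moved the median of all tested probes from -0.09 to -0.19, with 3179 probes rising and 3121 falling.

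High-diet changes in the 2 tissues were compared over 31234 probes tested in both. Of the risers in gut and in rest of body, 3808 and 2976 of these probes, 1152 were shared, against 363 for independent lists. Of the fallers, 5203 and 2213 probes, 1141 were shared, against 369. Another 169 probes fell in gut and rose in rest of body, and 67 did the reverse, against 496 and 270 for independent lists. The correlation of log2 changes across probes was 0.58 and their covariance 0.99. Gut and rest-of-body arrays of 1 number deviated together, which independent lists leave out. In 100 simulations of unchanged groups that kept the 2 arrays of a pool together, chosen after seeing the data, the correlation averaged 0.379 and reached 0.631, and the covariance averaged 0.10 and reached 0.41. The difference between the tissues in the high-diet effect was called for 7514 of 34917 probes. Of these, 3613 went upward and 3901 downward in gut relative to rest of body. Without the 2-fold threshold the numbers were 5615 and 4711. Har_00080807 rose in gut from 0.52 ± 1.49 to 3.85 ± 0.37 (SD, n = 4) while its rest-of-body level went from 3.89 ± 0.11 to -0.38 ± 2.49 (SD, n = 4), a difference of 7.60 (SE 1.35, limma adjusted p = 0.000531). Har_00079080 rose in gut from -4.27 ± 1.12 to 1.78 ± 0.30 (SD, n = 4) and differed between tissues by 6.87 (limma adjusted p = 0.00228). Har_00015172 differed by -9.74 (SE 2.33, limma adjusted p = 0.00425) and Har_00089891 by -9.51 (SE 2.33, limma adjusted p = 0.00496). The balance of directions depended on the scaling, which also changed which probes were called: 6914 were upward and 1411 downward with the spike-in reference, 5483 and 2584 with median centring, and 4600 and 3073 with quantile normalization. Of the 7514 probes, 5024, 6197 and 6421 were called under these settings. The median of all tested probes was -0.10 in the main setting and 0.33 with the spike-in reference. Averaged over the 2 arrays of each pool, the high diet raised 3404 probes and lowered 3429 (n = 4 pools per diet, chosen after seeing the data); with the spike-in reference these were 4031 and 2504.

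**Figure D2:**
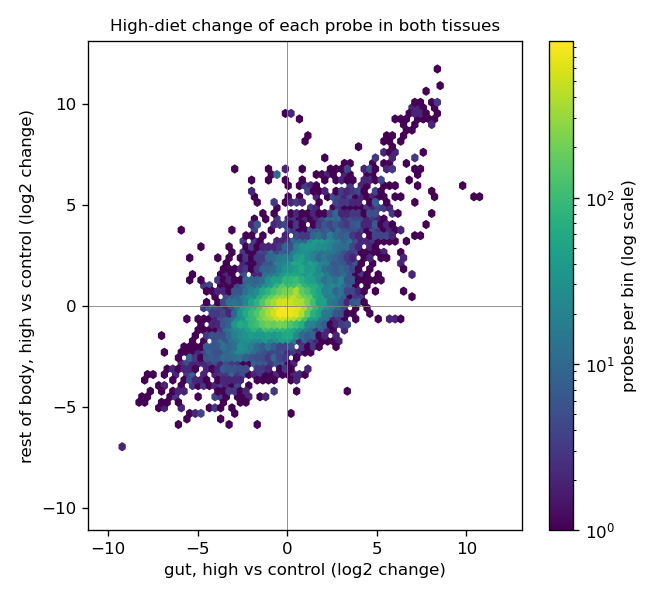
Log2 change on the high diet against control in gut (horizontal) and in rest of body (vertical) for each of the 31234 probes tested in both, as hexagons shaded by the number of probes on a log scale. The probes spread along a rising band, with a correlation of 0.58 across probes.

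On the low diet 391 probes were called in gut, of which 4 rose and 387 fell, and 347 in rest of body, of which 345 rose and 2 fell. These probes were dim, with a median level of -4.08 in gut and -4.04 in rest of body against -1.37 and -1.44 over all tested probes. Har_00008621 rose in gut by 2.13 on the log2 scale (SE 0.38, limma adjusted p = 0.0179) and Har_00008619 by 1.90 (SE 0.40, limma adjusted p = 0.0416), a call lost in 7 of the 8 fits that left out 1 array. Gut levels of Har_00008621 and Har_00008619 were close, with means of -2.80 and -2.84 on the low diet, so they may not be separate findings. Har_00138506 fell by 3.03 (SE 0.28, limma adjusted p = 0.000639) and Har_00083604 fell by 2.86 (SE 0.41, limma adjusted p = 0.00614). In rest of body Har_00015311 rose by 3.29 (SE 0.25, limma adjusted p = 0.000173) and Har_00119488 by 3.04 (SE 0.31, limma adjusted p = 0.000669), while Har_00137587 fell by 1.82 (SE 0.35, limma adjusted p = 0.0264) and Har_00122131 fell by 1.07 (SE 0.20, limma adjusted p = 0.0254). Of the 349 gut probes that fell and were tested in both tissues, 178 were among the 308 that rose in rest of body, against 3.44 for independent lists. The difference between tissues in the low-diet effect was called for 1044 probes, 15 upward and 1029 downward in gut relative to rest of body, and median centring moved the median of all tested probes from -0.02 to 0.17. Har_00231376 differed by 2.30 (SE 0.60, limma adjusted p = 0.0335), Har_00049447 by 1.35 (SE 0.34, limma adjusted p = 0.0257, and 0.0838 with the pool number as a replicate block), Har_00049347 by -4.72 (SE 0.50, limma adjusted p = 2.8e-06) and Har_00089573 by -4.66 (SE 0.27, limma adjusted p = 1.3e-09). Averaged over the 2 arrays of each pool, limma called 0 of 34917 probes on the low diet, with 2630 at an unadjusted p under 0.05. With normexp background correction 2 probes were called in gut and 75 in rest of body. Without gut control pool 4, 220 probes were called in gut, and with the replicate number as a block 237. On control probes outside the larval measurement, DCP_1_7 minus DCP_1_0 was -4.69 ± 0.16 on the low-diet gut arrays and -3.48 ± 0.07 on the control ones (SD, n = 4), and -3.49 ± 0.03 against -4.55 ± 0.14 in rest of body (SD, n = 4).

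Changes on the 2 diets shared the same control arrays. Log2 changes on the low and the high diet correlated across probes with 0.61 in gut and 0.57 in rest of body, against means of 0.51 and 0.49 in 100 simulations of unchanged groups. With 2 controls set against each diet in turn, the correlations averaged 0.46 and 0.39. Their covariance was 0.50 in gut and 0.45 in rest of body, against 0.13 and 0.13 in the simulations. In gut 85 probes were called in the same direction on both diets and in rest of body 119. The simulations gave 0 and 0 shared calls, but with a median of 0 calls per comparison they cannot show how many the shared controls add. For independent lists 64.4 probes lowered on both diets were expected in gut, where 82 were seen, and 36.3 raised on both in rest of body, where 118 were seen. Of the change of probes called on the high diet in gut, low-diet pools 1 to 4 showed medians of 34.0%, -8.41%, -2.67% and 68.6%. In rest of body these medians were 17.6%, 6.20%, -1.17% and 75.3%. The correlations, covariances and shared calls were not computed without low-diet pool 4. The simulations also drew on the deviations of that pool.

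The comparison of the 2 doses called 6504 probes in gut, 3273 higher and 3231 lower on the high diet, and 4061 in rest of body, 2428 higher and 1633 lower. Without the 2-fold threshold, 3946 were higher and 5286 lower in rest of body. The low-diet and high-diet slides differed in DCP_1_7 minus DCP_1_0 by 1.08 in gut and by -0.45 in rest of body, high minus low (exact permutation p = 0.0286 for each, two-sided). For DCP_22_7 minus DCP_22_0 these differences were 0.64 in gut (exact permutation p = 0.0571) and -0.16 in rest of body (exact permutation p = 0.229). Of the 308 probes tested here that rose in rest of body on the low diet, 206 were higher and 0 lower in gut on the high than on the low diet (camera adjusted p = 6.13e-36, and adjusted p = 0.000941 with an estimated correlation). Of the 349 that fell in gut on the low diet, 3 were higher and 86 lower in rest of body on the high than on the low diet (camera adjusted p = 1.41e-13, and adjusted p = 0.116 with an estimated correlation). These 2 sets were chosen after seeing the data. Har_00015936 was higher by 6.29 in gut (SE 1.68, limma adjusted p = 0.0174) and Har_00042388 by 5.08 (SE 0.90, limma adjusted p = 0.00394). Har_00094261 fell by 7.18 (SE 1.82, limma adjusted p = 0.0145) and Har_00221632 fell by 7.11 (SE 1.75, limma adjusted p = 0.0131). Levels of Har_00094261 and Har_00221632 ran close together over the arrays, such as 1.35 and 1.07 in gut high-diet pool 2. They may not be separate findings. In rest of body Har_00028831 was higher by 7.01 (SE 2.29, limma adjusted p = 0.0439) and Har_00001837 by 6.58 (SE 2.05, limma adjusted p = 0.0379), both lost in 6 of the 8 fits that left out 1 array. Har_00028831 and Har_00001837 also rose and fell together over the arrays and may not be separate findings. Har_00064268 fell by 5.47 (SE 1.31, limma adjusted p = 0.0173) and Har_00116712 fell by 4.29 (SE 1.05, limma adjusted p = 0.0182). With the spike-in reference 7260 probes were higher and 1066 lower in gut, and the median of all tested probes moved from 0.05 to 0.48. Low-diet pools differed from each other on a scale where 0 is the control mean and 1 the high-diet mean, computed without the array placed on it. In gut pools 1 to 4 lay at 0.355, -0.0468, -0.0282 and 0.762, and in rest of body at 0.252, 0.0608, 0.000663 and 0.744. Without pool 4, 9785 probes were called in gut and 6348 in rest of body. Without low-diet pool 2 the counts were 3950 and 1628, without low-diet pool 3 they were 4234 and 1640, and without high-diet pool 3 they were 4010 and 1905; without high-diet pool 4 the rest-of-body count was 1728.

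**Figure D3:**
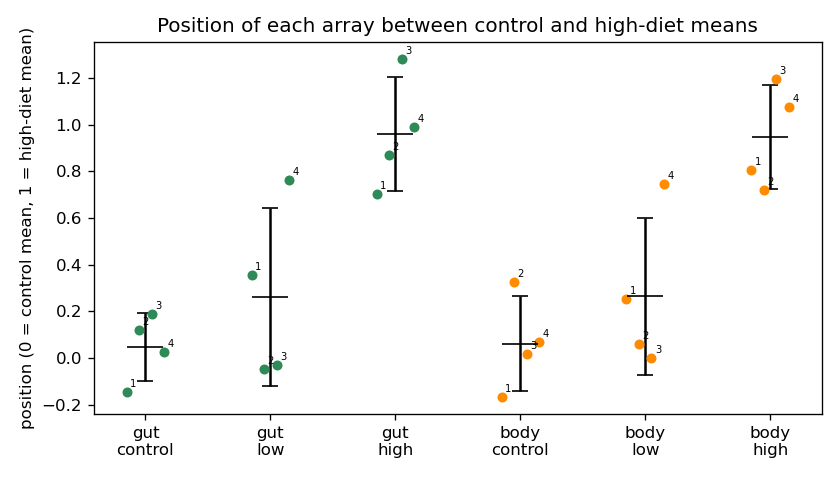
Position of each array (points, numbered by pool) between the control mean at 0 and the high-diet mean at 1 of its tissue, with the group mean and SD (black bars, n = 4). Low-diet pool 4 lies at 0.762 in gut and 0.744 in rest of body, while the high-diet arrays lie between 0.701 and 1.28.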

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

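Tests in this part on control probes, positions of pools and probes called in the other tissue were chosen after their results were seen. So were those on calls without low-diet pool 4. The splits of samples were planned, but the averages over tissues, to which they were also applied, were chosen after seeing the data. In these splits 1 of 35 is the smallest share possible, and the shares were not adjusted over the results. The splits mix arrays of different slides, so they test how pools were grouped and do not measure how slides vary. Keeping together or parting the arrays of a pool in the splits rests on the test of pairing, also chosen after its result was seen.

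The change from control to diet slides differed between gut and rest-of-body arrays, by a direct test of the difference, for 1044 probes on the low diet and 7514 on the high diet. Among those named on the low diet the differences were 2.30 for Har_00231376, 1.35 for Har_00049447, -4.72 for Har_00049347 and -4.66 for Har_00089573 on the log2 scale. The call on Har_00049447 was lost with the pool number as a block (limma adjusted p = 0.0838). On the high diet they were 7.60 for Har_00080807, 6.87 for Har_00079080, -9.74 for Har_00015172 and -9.51 for Har_00089891. With the gut and rest-of-body arrays of a pool kept together, 1 of 35 splits of the pools, the real one, gave as many probes on each diet. The highest other counts were 11 and 2, so chance in how pools were grouped was excluded for both. Each diet and tissue has its own slide, so a tissue difference in the effect of diet and differences between slides cannot be told apart. On the low diet 1029 of the 1044 went downward in gut relative to rest of body, the direction in which DCP_1_7 minus DCP_1_0 differed between the same slides (-1.20 in gut and 1.06 in rest of body).

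The low-diet calls coincided with a difference between slides in control probes that no comparison of diets used: DCP_1_7 minus DCP_1_0 differed by -1.20 between the low-diet and control slides in gut and by 1.06 in rest of body (exact permutation p = 0.0286 for each, two-sided, the smallest that 4 against 4 arrays allow; adjusted p = 0.05 over 14 such tests), while DCP_1_0 stayed between 0.05 below and 0.03 above the spike-in probe E1A_r60_1 on all 24 arrays. These p-values rest on the spread of arrays within slides and do not measure how slides vary. Both differences have the direction of most calls, 387 of 391 in gut and 345 of 347 in rest of body. Hybridization differing between slides may account for these calls. The 4 probes that rose in gut and the 2 that fell in rest of body went the other way. On the high diet these probes changed in the same direction as on the low diet, with control arrays shared by both diets. Their median high-diet change was 1.93 in gut, where 3 were called, and -2.31 in rest of body, where 1 was called. The sets used below for an effect that grows with dose do not include these probes. DCP_22_7 minus DCP_22_0 differed by -0.52 in gut (exact permutation p = 0.0286) and by 0.22 in rest of body (exact permutation p = 0.0857). Low-diet pool 4 as the sole cause was excluded, since 372 and 344 probes were called without it. An effect of gossypol that grows with dose was argued against as the whole cause: the 308 probes that rose in rest of body had a median change in gut of -1.49 on the low diet and -0.061 on the high diet (quartiles -0.60 and 0.53), and the 349 that fell in gut had 1.18 and 0.56 in rest of body (quartiles 0.14 and 0.91 on the high diet), while gossypol acting at the low dose alone cannot be told apart from the slide, as each of the 6 slides held 1 group. Chance was not excluded for the 2 low-diet counts, as 2 of 35 splits gave as many probes in gut (391 against at most 493) and 2 of 35 in rest of body (347 against at most 805), the real split among the 2 in each tissue. The highest other split in gut put low-diet pools 1 and 4 with control pools 3 and 4. In rest of body it put low-diet pool 1 with control pools 1, 3 and 4. The median over the other splits was 0 probes in each tissue.

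Low-diet pool 4 lay near the high-diet pools in both tissues, at 0.762 in gut. A swap with a high-diet pool was argued against, since the lowest high-diet array lay at 0.701 and none was out of place, and so was the position on the slide, since the control arrays at that position lay at most at 0.0703. Pools that differ in the same state in both tissues may account for it: positions of gut and rest of body, centred within diets, correlated over 12 pools with Pearson r = 0.891 (exact permutation p = 0.00181) and Spearman rho = 0.783 (exact permutation p = 0.0119), and without the 2 pools farthest from the median with r = 0.689 (exact permutation p = 0.0463) and rho = 0.612 (exact permutation p = 0.106). A wrong label, or a pool from outside the low-diet group, stays open. The 35 splits for high against low excluded chance in how pools were grouped (1 of 35 in each tissue). The counts were 6504 probes against at most 2683 in gut and 4061 against at most 1874 in rest of body. In both tissues the highest other split put low-diet pool 4 with high-diet pools 2 to 4 and high-diet pool 1 with the low diet.

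The high-diet calls were not explained by the stringency read from DCP_1_7 in gut, where the high-diet slide differed from the control slide by -0.12, against -1.20 for the low-diet slide, and 9671 probes were called. In rest of body the difference was 0.61 (exact permutation p = 0.0286) against 1.06 for the low-diet slide, yet the 5999 called probes showed a median of 17.6%, 6.20%, -1.17% and 75.3% of their high-diet change in low-diet pools 1 to 4, so stringency was excluded as the whole cause there, and a contribution stays open. For DCP_22_7 minus DCP_22_0 the high-diet and control slides differed by only 0.06 in rest of body (exact permutation p = 0.686), so the difference there rests on DCP_1_7. Other differences between the 6 slides cannot be told apart from diet. Chance in how pools were grouped was excluded, as 1 of 35 splits gave as many probes in gut (highest other 9) and 1 of 35 in rest of body (5999, highest other 19). The same held for the averaged comparison (6833, highest other 1; 1 of 35).

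Gut against rest of body gave 15338 probes, and the highest other of the 8 splits that part all 4 pairs of arrays from 1 pool gave 0, but 8 splits are too few for a share under 0.05. The other splits leave pairs together and gave at most 522. The averaged low diet gave 0 probes, so all 35 of 35 splits gave as many by construction and decide nothing; the highest gave 245.

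Single arrays stood apart from their group in 11 of 117 groups of 4 values tested, of which chance flags about 5 percent. The 75th percentile signal was 685 in rest-of-body control pool 4 and 704 in rest-of-body low-diet pool 3. In gut, low-diet pool 3 had levels of -2.20 for Har_00008621 and -2.34 for Har_00008619, and low-diet pool 1 had -4.98 for Har_00138506. In rest of body, control pool 4 had -4.89 for Har_00015311 and -1.90 for Har_00050436, low-diet pool 4 had -1.53 for Har_00119488, -7.15 for Har_00231376 and -5.86 for Har_00049447, and control pool 2 had 6.75 for Har_00175686.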

How the results depend on the processing

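The spike-in scaling, the fits without low-diet pool 4 and the averages over tissues were chosen after seeing the data; the other settings were planned. The low-diet calls lay on dim probes; with no filter on these, 405 were called in gut and 387 in rest of body. Counts are given for settings that moved them over 1.5 times; all other counts stayed within that.

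For gut low against control, main count 391, quantile normalization and the authors' table gave 258 each, normexp 2, the strict filter 169 (fewer probes tested), treat 85 (a stricter test), only the arrays of the 2 groups 160 (fewer arrays), all 24 arrays 636, spike-in scaling 228 and the replicate block 237. For rest of body low against control, main count 347, normexp gave 75, the strict filter 224 and treat 113. For the tissue difference in the low effect, main count 1044, normexp gave 188, the strict filter 540 and treat 582. The averaged low diet gave 2 with the authors' table and 4 with the 24 arrays taken as separate samples.

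For gut high against control, main count 9671, normexp gave 4744, adjusted p alone 15958 and treat 4030. For gut high against low, main count 6504, normexp gave 2116, adjusted p alone 11327, treat 1055, array weights 11271 and the fit without low-diet pool 4 9785. For rest of body high against control, main count 5999, adjusted p alone gave 13069 and treat 1751. For rest of body high against low, main count 4061, adjusted p alone gave 9232, treat 114, only the arrays of the 2 groups 2084, array weights 6113 and the fit without low-diet pool 4 6348. For the tissue difference in the high effect, main count 7514, normexp gave 3838 and treat 2383. Gut against rest of body, main count 15338, gave 10019 with the strict filter. The averaged high diet, main count 6833, gave 4096 with normexp, 3975 with the strict filter, 15089 with adjusted p alone and 1756 with treat. Where no construction is named, the cause was not tested.

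Leaving out 1 array moved the counts over 220 to 420 for gut low, 7571 to 9975 for gut high, 3950 to 9785 for gut high against low, 248 to 344 for rest of body low, 4420 to 6820 for rest of body high and 1628 to 6348 for rest of body high against low. The ranges were 924 to 1121 and 6410 to 8050 for the tissue differences on the low and high diet, and 14370 to 15837 for gut against rest of body. For the averages both arrays of a pool were left out, with 0 to 0 for the low diet and 5200 to 7518 for the high diet. The values beyond 1.5 times came without gut control pool 4 (220), and for high against low without gut high-diet pool 3 (4010), without low-diet pools 2 (3950 and 1628), 3 (4234 and 1640) and 4 (9785 and 6348), and without rest-of-body high-diet pools 3 (1905) and 4 (1728).

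The pool number as a block across tissues gave 1194, 9182 and 15966 probes for the low and high tissue differences and gut against rest of body, and changed no count over 1.5 times. Across diets within a tissue the number only names an array: correlations of deviations ran from -0.41 to 0.292, and the replicate block moved gut low to 237 and no other count over 1.5 times. None of the 40 calls on named probes changed direction under the settings run; 18 were lost under treat, 9 with normexp, 9 with only the groups compared, 6 with the replicate block, 6 with spike-in scaling, 5 without low-diet pool 4, 3 with no filter on dim probes and 1 with array weights. With all 24 arrays 2 of 24 were lost, with the strict filter 1 of 21, and in fits that left out 1 array, or 1 pool for the averages, 73 of 384. The slide as a block, 1 probe per gene and the gene lists were not run.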

Other observations

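The test of pairing in this part was chosen after its result was seen.

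Some bright probes were much lower in some high-diet pools than in others, in both tissues. The example given here stayed well above background on all 4 high-diet arrays of each tissue. Har_00094261 lay at 5.86, 1.35, -4.71 and -3.88 in gut high-diet pools 1 to 4 and at 4.91, 6.46, -0.88 and -1.52 in rest of body, against 6.86 ± 0.20 and 6.27 ± 0.36 (SD, n = 4) on the control diet. Over the probes tested in both tissues, 96 spread more than 64-fold among the 4 high-diet pools of each tissue. The same pool was lowest in both tissues for 61 of them, pool 3 in 47, and highest in both for 10. For pools that vary independently in the 2 tissues 24 are expected on average. Probes of an array are not independent, so counts beyond such averages may come from 1 pool and do not measure chance. On the low diet 117 probes spread as widely, and the same pool was lowest in both for 56 and highest in both for 89, pool 4 in 82, against 29.2. On the control diet 16 probes did so, the same pool lowest in both for 4 and highest in both for 5, against 4.

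Har_00210099, which rose on the high diet, stood at 6.69 in gut and 6.37 in rest of body of low-diet pool 4. In low-diet pool 1 it stood at -2.24 in gut and 6.64 in rest of body, and in pools 2 and 3 between -3.69 and -2.46 in both tissues. Har_00089891 stood at 3.08 and 5.58 in rest of body of low-diet pools 1 and 4 and at -4.82 and -4.50 in pools 2 and 3.

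Gut and rest-of-body arrays of 1 number may come from the same larvae: each of the 12 gut arrays correlated best with the rest-of-body array of its own number among the 4 of its diet, with deviations from the group means taken over 31234 probes. Some margins were thin, with 0.195 against 0.180 in low-diet pool 1 and 0.200 against 0.190 in control pool 4.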
